A study of Mus musculus with 16 samples.

How the data were processed

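RNA from the cerebral cortex of Dyrk1a wild-type and heterozygous mice at postnatal day 0 and postnatal day 7 was measured on Affymetrix mouse GeneChip arrays after a two-cycle labelling of 100 ng of total RNA, per the labels. There were 16 arrays, 4 in each of 4 groups. The deposited values are 1 log2 signal per probe set and array, already corrected, normalized and summarised by the authors. The method of that normalization is not given in the sources used here. Array medians were nearly equal, and the 16 value distributions were not identical. Raw image files were not used here, and the table held 0 control probe sets. A planned test of RNA integrity from the 3' and 5' control probe sets, and its use as a covariate, could therefore not be run.

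Of 45037 probe sets, 34945 were paired with exactly 1 gene symbol by the annotation table, 932 with several and 9160 with none. Of those with 1 gene, 34741 were matched to the reference gene table (GRCm38.p6) by gene ID. A gene was represented by its probe set of highest mean over all 16 arrays, which gave 18193 genes. Genes whose mean lay below the 40th percentile of all probe sets (log2 5.15) were left out, which left 12801.

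Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with 4 group means was fitted to all 16 arrays with lmFit and eBayes (12 residual and 4.59 prior degrees of freedom, no intensity trend), two-sided. Contrasts were heterozygous minus wild type at each age, the difference and the mean of these effects, and P7 minus P0 in each genotype. A gene passed with a Benjamini-Hochberg adjusted p under 0.05 over the genes tested within a contrast, which is what "called" and "passed" mean in the results. Differences of Dyrk1a and of the developmental score were also tested by exact two-sided permutation of 4 arrays against 4 (70 arrangements, smallest p = 0.0286).

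Gene lists were written from general knowledge: neuron types and progenitors, synapse and channel genes, signalling near the kinase, other cell types and brain regions a cortical sample can hold, and gene families. The 37 lists with at least 5 measured genes were tested with camera (preset correlation 0.01), adjusted over the lists within a contrast. Camera with an estimated correlation and fry were run as alternatives. Each list also received counts of genes passing over all genes tested and adjusted over the list alone. The lists, contrasts, tests and the rule for naming genes were chosen before the data were examined. That rule took Dyrk1a, up to 10 genes per direction with the largest change among those that passed and whose groups did not overlap (for the interaction and the mean effect, those that passed), filled with the lowest p where fewer qualified, and up to 4 genes per list passing adjusted over the list alone. For age only the first 10 per direction and 4 per list were used. Most genes named are from this rule, and a selection of those it gave is printed.

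Replicate numbers were treated as pairing arrays of 1 age, since the deviations of equally numbered arrays from their group means correlated at every number (r between 0.115 and 0.599, all over 0.1). The replicate number within age was therefore used as a block in an alternative fit. For the comparisons of ages this replicate block was the number shared across both ages, which those correlations within age do not cover. A second block, replicates 1 and 2 against replicates 3 and 4, was added after the arrays were seen to split that way. Its groups are called array batches, and the labels do not say what they stand for. Arrays of different groups in the same batch had a median deviation r of 0.343, and those in different batches -0.340. The correlations at equal numbers therefore do not tell pairing by number apart from the batches, and the pairs remain an assumption. Tables for other choices covered quantile normalization again, median centring, other filters on dim genes, the mean of all probe sets of a gene, removal of cross-hybridizing probe sets, an intensity trend with robust fitting, only the 8 arrays compared, the middle part of the sample description code as a block, the Y-linked level as a covariate, and leaving out each array in turn.

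The procedure was tested on simulated data of the same size, with 200 of 12801 genes changed at P0. It recovered 55.5% of genes changed by 0.5 on the log2 scale (6.72% of calls false) and 97% of those changed by 1 (6.28% of calls false), and called 1 shifted list and 0 others. The simulated noise was independent between genes and held no array batches, so these rates of false calls do not carry over to the real arrays. There, wrongly labelled splits that part every replicate pair gave up to 14 called lists at P0. Other groupings of the arrays were counted over all 35 splits of 8 arrays into 4 and 4, or over 100 random draws within age, and again over those that part every replicate pair. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.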

Results

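Messenger RNA was measured in the cerebral cortex of mouse pups carrying either 2 intact copies of Dyrk1a (wild type) or 1 (heterozygous). Dyrk1a encodes a dual-specificity protein kinase whose dosage is altered in Down syndrome and in an intellectual disability syndrome. Pups were taken on postnatal day 0 (P0) and postnatal day 7 (P7). Each of the 4 groups held 4 arrays, giving 16 arrays in all. The table held 1 log2 signal for each of 45037 probe sets per array, with values between 2.24 and 14.49. Array medians lay between 5.84 and 5.86. Within groups, arrays correlated across the 12801 genes tested with r between 0.979 and 0.995. An array has no read depth, so precision was limited by the number of arrays. All differences below are log2 differences, heterozygous minus wild type unless stated, with the standard error (SE) of the fit and n = 4 arrays per group, and 12801 genes were tested.

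Sex was not among the labels. The Y-linked gene Eif2s3y was high (log2 10.28 or more) on 5 arrays and low (3.49 or less) on 11. High values were found on 1 array each of the wild-type P0, heterozygous P0 and wild-type P7 groups and on 2 of the heterozygous P7 group. The arrays also split by replicate number. Replicates 1 and 2 separated from replicates 3 and 4 of every group on the second principal component, the first holding 61.8% of the variance. With the 4 groups in the model, 5087 genes differed between these array batches. Each group had 2 arrays in each batch, so counts, list medians and scores were also computed within each batch. Of the called lists, 17 of 18 at P0, 12 of 15 at P7 and 16 of 17 for the mean of both ages had medians of 1 sign in both batches, and the exceptions are given below.

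The first comparison asked whether the targeted gene itself differed. No difference in Dyrk1a signal between arrays labelled heterozygous and wild type passed the test. The most intense of its 3 probe sets averaged 7.98 ± 0.15 (SD, n = 4) in wild type and 8.17 ± 0.10 in heterozygotes at P0, a difference of 0.19 (SE 0.09, exact permutation p = 0.0857, two-sided). At P7 its difference was 0.05 (exact p = 0.40). The next most intense probe set differed by 0.47 at P0 (exact p = 0.0857) and by -0.48 at P7 (exact p = 0.0571). The dimmest probe set differed by 0.12 and -0.06 (exact p = 0.486 and 0.686). The last value changed sign without heterozygous P7 replicate 1 (0.0099) or replicate 2 (0.038). Which part of the gene each probe set measures is not given in the sources used here, so these values do not check the genotype labels.

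At P0, the question was which genes differ at birth when 1 copy of Dyrk1a is disrupted. The genes that fell most included Gpr6 (-1.06, SE 0.22), an orphan receptor of striatal neurons, and Ptger4 (-0.98, SE 0.13), a prostaglandin E2 receptor. Itih3 (-0.85, SE 0.13), Timp4 (-0.84, SE 0.12), an inhibitor of metalloproteinases, Slc6a7 (-0.80, SE 0.12), the brain proline transporter, and Mal2 (-0.75, SE 0.12) also fell. Among the genes that rose were the histone H3.3 gene H3f3b (0.98, SE 0.19), Cyp11a1 (0.89, SE 0.14), which starts steroid synthesis from cholesterol, Pik3r3 (0.75, SE 0.13), a regulatory subunit of PI3-kinase, and the p53-induced gene Trp53inp1 (0.67, SE 0.12). The DNA replication gene Gins1 (0.61, SE 0.10), the proliferation marker Mki67 (0.60, SE 0.12) and Tbr1 (0.57, SE 0.12), a transcription factor of deep-layer neurons, rose too. Their adjusted p lay between 0.00741 (Ptger4) and 0.0374 (Gpr6).

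Genes of dividing cells and of neurogenesis were higher at P0 as lists. Of 29 measured S to M phase genes, 1 rose, none fell and 28 did not pass over all genes. When adjusted over the list alone 10 rose, and all 29 differences were positive (median 0.28). Besides Mki67, the mitotic genes Top2a (0.61) and Bub1 (0.61) and the survivin gene Birc5 (0.35) had positive values that did not pass over all genes. The list's camera adjusted p was 7.45e-16, and adjusted p = 0.0531 with an estimated correlation. Of 12 genes of intermediate progenitors and neurogenesis, 0 passed over all genes in limma (6 rose adjusted over the list alone), with a median of 0.30. Neurog2, a proneural transcription factor, had 0.64 and Btg2 0.36. The adjusted p was 4.05e-06, and adjusted p = 0.0531 with an estimated correlation. At replicates 1 and 2 the medians of these 2 lists were 0.25 and 0.21, and at replicates 3 and 4 they were 0.34 and 0.43.

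Genes of the inhibitory postsynapse, presynaptic vesicles, voltage-gated channels, astrocytes and the oligodendrocyte lineage were lower at P0 as lists. The lists of glutamate receptors and of microglia were not called. Of 14 genes of GABA receptors and the inhibitory postsynapse, 1 fell and 13 did not pass. The gene that fell was Slc12a5 (-0.46, SE 0.09), the chloride transporter that sets the response to GABA in mature neurons. Adjusted over the list alone 3 fell, the others being the receptor subunits Gabrg1 (-0.72) and Gabrb1 (-0.40). This list was the only one called at P0 with an estimated correlation (adjusted p = 0.0359, and 0.000241 with the preset one), and that call was lost with the array batch as a block (adjusted p = 0.0589 with an estimated correlation). Of 35 genes of presynaptic vesicles 2 fell, the endocytic GTPase Dnm1 (-0.41, SE 0.08) and Doc2a (-0.56, SE 0.12), and 6 adjusted over the list alone (adjusted p = 1.24e-05, and adjusted p = 0.0653 with an estimated correlation). Of 39 voltage-gated channel genes 2 fell, the potassium channels Kcnc4 (-0.61, SE 0.12) and Kcna2 (-0.41, SE 0.08), also 2 adjusted over the list alone (adjusted p = 0.00326, and adjusted p = 0.12 with an estimated correlation). The postsynaptic scaffold gene Shank3 fell by 0.58 (SE 0.10). Of 25 astrocyte genes 2 fell, Itih3 and the water channel Aqp4 (-0.62, SE 0.12), and 5 adjusted over the list alone (adjusted p = 0.000968, and adjusted p = 0.12 with an estimated correlation). Of 16 genes of myelinating oligodendrocytes 1 fell, Cnp (-0.64, SE 0.13), and 4 adjusted over the list alone. These included Mbp, the gene of myelin basic protein (-0.91, adjusted p = 0.129 over all genes). That list's adjusted p was 0.000492, and adjusted p = 0.0531 with an estimated correlation. Of 14 oligodendrocyte precursor genes 1 fell, Gpr17 (-0.56, SE 0.12), and 2 adjusted over the list alone (adjusted p = 0.015, and adjusted p = 0.12 with an estimated correlation).

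Genes of sterol synthesis and markers of the striatum were lower at P0 as well. Of 19 sterol genes 1 fell, Mvd (-0.65, SE 0.13), an enzyme of the mevalonate pathway, and 7 adjusted over the list alone, among them Idi1 (-0.37). The list's median was -0.23 (adjusted p = 3.04e-05, and adjusted p = 0.0531 with an estimated correlation). Of 19 striatal markers 2 fell, Gpr6 and the substance P precursor Tac1 (-0.59, SE 0.09), and 4 adjusted over the list alone. The enkephalin precursor Penk had -0.70 (adjusted p = 0.0567). The list's adjusted p was 0.000146, and adjusted p = 0.0531 with an estimated correlation. The medians of the striatal list were -0.10 at replicates 1 and 2 and -0.34 at replicates 3 and 4. The 8 other lists called at P0 were lost with an estimated correlation (adjusted p between 0.12 and 0.494 with an estimated correlation). They were splicing factors (median 0.13), G1 regulators (0.15), kinases of the DYRK, CLK and HIPK families (0.11), autism and intellectual disability genes (0.05), ribosomal proteins (0.06), oxidative phosphorylation (-0.11), markers of thalamus, hypothalamus and midbrain (-0.20), and choroid plexus and ependyma (-0.20). Over all genes, their only members that passed were Tbr1 and Shank3, both in the autism list. Among genes adjusted over the list alone, 5 of choroid plexus and ependyma and 1 of thalamus, hypothalamus and midbrain fell, and 1 G1 regulator, Ccnd2 (0.38), rose. The choroid plexus median was -0.38 within replicates 1 and 2 and 0.06 within replicates 3 and 4. With the replicate block that list was not called (adjusted p = 0.0797), and glutamate receptors were (adjusted p = 0.0204, and 0.0675 without the block). Without the block, glutamate receptors were not called with an estimated correlation either.

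In total 88 genes passed at P0, 18 higher and 70 lower, and 1640 had an unadjusted p under 0.05. With the mean of all probe sets of a gene 137 passed, 52 higher and 85 lower, and of the probe sets tested singly 85 passed, 38 higher and 47 lower. The share lower was thus 79.5%, 62.0% and 55.3%. With the replicate number as a block 386 passed, including the 88 and also Penk (adjusted p = 0.0102), Top2a (0.0112), Bub1 (0.0182), Btg2 (0.0285), Gabrg1 (0.00812) and Gabrb1 (0.0147). When only the 8 arrays from P0 were fitted, 0 genes passed in limma, so the calls rest on the spread estimated over all 16 arrays. Within replicates 1 and 2 alone 1 gene passed, and within replicates 3 and 4 alone 0 did. The count fell to 14 without wild-type replicate 1, 14 without wild-type replicate 4, 18 without heterozygous replicate 2, 44 without heterozygous replicate 1 and 53 without wild-type replicate 3. Of the genes named here as passing, Cyp11a1, Gins1, Itih3, Mal2, Ptger4, Slc6a7, Tac1 and Timp4 passed whichever of the 8 arrays was left out. The others each lost the call without wild-type replicate 1 and without wild-type replicate 4. Of 85 other probe sets of the called genes, 73 had the same sign as the one tested. Only 30 had that sign at an unadjusted p under 0.05. Rpf1 (0.58) was the 1 gene called at P0 with another probe set of opposite sign at an unadjusted p under 0.05. For the genes called at P7, 22 of 30 other probe sets had the same sign (11 at such a p). For the mean of both ages 263 of 329 did (140 at such a p), with Rpf1 and Vps13c having an opposite one.

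At P7, the question was which genes differ a week later. Ddit4, an inhibitor of mTORC1 induced by stress, rose by 1.31 (SE 0.20), from 8.37 ± 0.39 (SD, n = 4) in wild type to 9.68 ± 0.24. The ribonucleotide reductase gene Rrm2 (0.71, SE 0.14), the MAX-binding repressor Mxd4 (0.61, SE 0.11), the glycosyltransferase B3gnt5 (0.57, SE 0.07) and the cyclin gene Ccnd2 (0.50, SE 0.09) also rose. Sox11, a transcription factor of immature neurons (0.52), and the chromatin gene Hmgb2 (0.64) did not pass. P2ry12 (-1.21, SE 0.20), a purine receptor of microglia, Penk (-1.05, SE 0.16) and the somatostatin gene Sst (-1.0, SE 0.16) fell. Sgpp2 (-0.97, SE 0.18), Lgi3 (-0.83, SE 0.13), the orphan receptor gene Gpr83 (-0.76, SE 0.11), the myelin gene Mobp (-0.69, SE 0.10) and the collagen gene Col25a1 (-0.66, SE 0.12) fell too. Adjusted p lay between 0.00855 (B3gnt5) and 0.0486 (Rrm2) for those that rose or fell.

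Genes of inhibitory neurons, channels and the striatum were lower at P7 as lists, and none of the 15 lists called at P7 was called with an estimated correlation. Of 23 cortical interneuron genes 2 fell, Sst and the vesicular GABA transporter Slc32a1 (-0.59, SE 0.12). Of its genes adjusted over the list alone, 5 fell and 1, Dlx2 (0.52), rose. Vip had -0.81 and did not pass over all genes. The list's adjusted p was 0.0467, and adjusted p = 0.291 with an estimated correlation. Its median was -0.35 within replicates 1 and 2 and -0.05 within replicates 3 and 4. Of 39 voltage-gated channel genes 2 fell, the sodium channel subunits Scn4b (-0.83, SE 0.16) and Scn2b (-0.71, SE 0.12), and 4 adjusted over the list alone (adjusted p = 0.024, and adjusted p = 0.261 with an estimated correlation). Of 19 striatal markers 2 fell, Penk and Tac1 (-0.48, SE 0.09), and 8 adjusted over the list alone. Pdyn had -0.49 and Ppp1r1b, which encodes DARPP-32, had -0.70. The list's adjusted p was 9.17e-05, and adjusted p = 0.107 with an estimated correlation. Of 14 inhibitory postsynapse genes 0 passed over all genes in limma (3 fell adjusted over the list alone, including Slc12a5 at -0.40 and Gabrd at -0.43), with adjusted p = 0.00748, and adjusted p = 0.107 with an estimated correlation.

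Glial, sterol and cell cycle lists had medians of the same sign at P7 as at P0. Of 25 astrocyte genes 0 passed over all genes in limma, and 7 fell adjusted over the list alone (median -0.17, adjusted p = 0.000517, and adjusted p = 0.172 with an estimated correlation). Examples were Acsbg1 (-0.60), Slc7a10 (-0.52), Aldoc (-0.52) and S100b (-0.78). Of 16 genes of myelinating oligodendrocytes 1 fell, Mobp, and 5 adjusted over the list alone, Mbp among them (-0.87). The list's adjusted p was 0.00131, and adjusted p = 0.114 with an estimated correlation. Of 19 sterol genes 0 passed over all genes in limma, and 2 fell adjusted over the list alone, including Tm7sf2 (-0.48). That list's adjusted p was 0.00598, and adjusted p = 0.225 with an estimated correlation. Of 29 S to M phase genes 1 rose, Rrm2, over all genes and over the list alone (median 0.12, adjusted p = 7.53e-05, and adjusted p = 0.291 with an estimated correlation). The 7 other lists called at P7 were upper-layer excitatory neurons (median 0.13), histones (0.11), olfactory bulb (0.13), intermediate progenitors (0.07), G1 regulators (0.03, with Ccnd2 the 1 gene that rose), presynaptic vesicles (-0.15) and oxidative phosphorylation (-0.12). Medians within replicates 1 and 2 and within replicates 3 and 4 differed in sign for histones (-0.03 and 0.28), olfactory bulb (-0.0033 and 0.26) and G1 regulators (0.05 and -0.01). With an estimated correlation the adjusted p of these 7 was between 0.114 and 0.307. Except for Ccnd2 none of their genes passed over all genes in limma. Adjusted over the list alone 2 presynaptic genes fell, and 1 intermediate progenitor gene rose and 1 fell. With the replicate block the intermediate progenitor list was not called (adjusted p = 0.0649), and radial glia were (adjusted p = 0.0349, and 0.0702 without the block). Without the block, radial glia were not called with an estimated correlation either.

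In total 28 genes passed at P7, 6 higher and 22 lower, and 1584 had an unadjusted p under 0.05. The share lower was 78.6%, and 66.7% with quantile normalization again. With the replicate number as a block 101 passed, including Sox11 (adjusted p = 0.0293), Hmgb2 (0.0160), Vip (0.0258), Pdyn (0.0427), Ppp1r1b (0.0219), Acsbg1 (0.0422), Aldoc (0.0462) and Tm7sf2 (0.0422). Fewer passed in other fits: 7 with only the 8 arrays from P7, 12 with the middle part of the sample description code as a block, and 10 with the Y-linked level as a covariate. Within replicates 1 and 2 alone 3 genes passed, and within replicates 3 and 4 alone 3. Without wild-type replicate 4, 2 or 1 the count was 3, 4 or 7. Without heterozygous replicate 4, 1, 3 or 2 it was 7, 12, 13 or 16. B3gnt5 was the only named gene that passed whichever of the 8 arrays was left out. Ddit4, Penk and Mobp lost their call only without wild-type replicate 4, Gpr83 without wild-type replicate 2 or 4, and Sst without wild-type replicate 1 or 2. P2ry12 lost it without wild-type replicate 1, 2 or 4, and Lgi3 without wild-type replicate 1 or 2 or heterozygous replicate 4. The other genes named as passing lost it in 5 to 8 of the 8 fits.

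**Figure D1:**
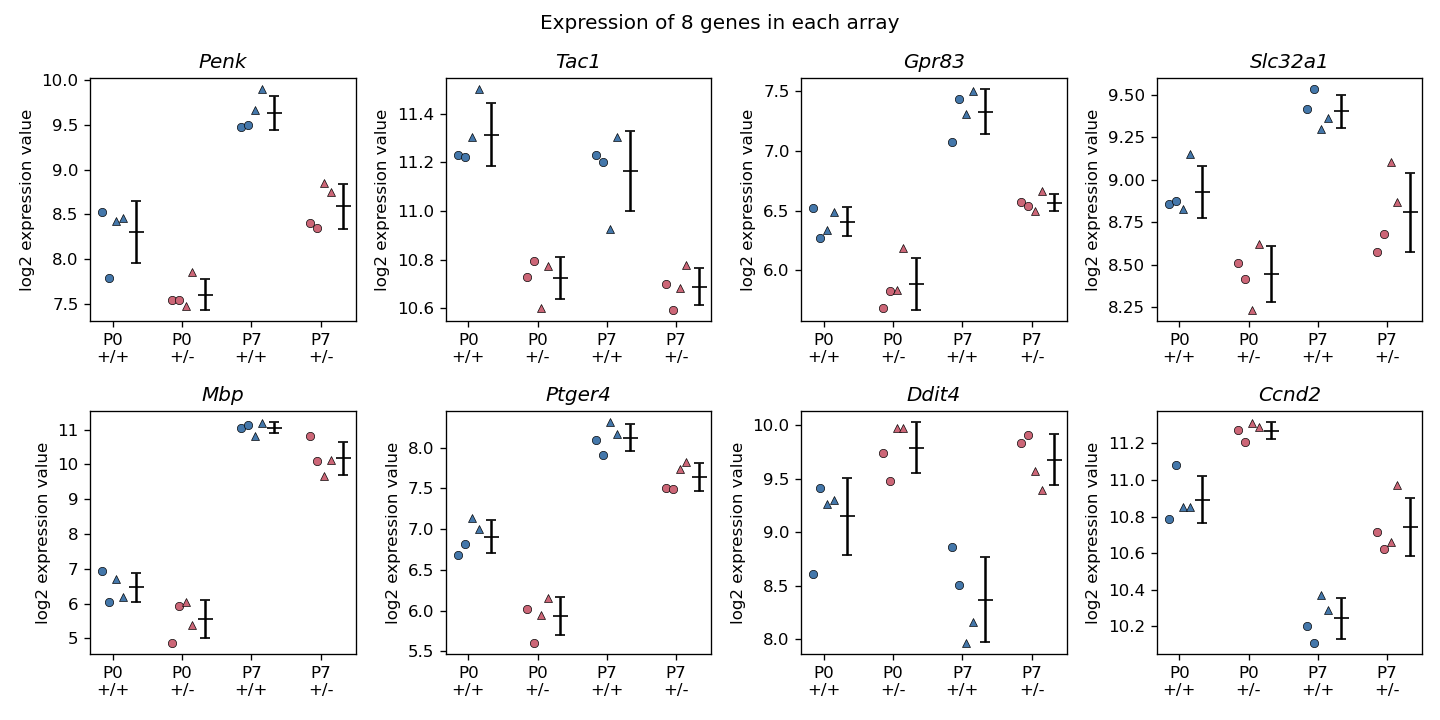
Expression (log2) of 8 genes on each of the 16 arrays by age and genotype; circles are replicates 1 and 2, triangles replicates 3 and 4, and bars show the mean and SD of 4 arrays. For Ddit4 the P7 means were 8.37 in wild type and 9.68 in heterozygotes, and for Penk they were 9.64 and 8.59.

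The mean of both genotype effects used all 16 arrays and asked which genes differed when the ages were averaged. A difference at 1 age alone can pass it, so it does not show that the ages shared a difference. Ddit4 (0.97, SE 0.14), Pik3r3 (0.69, SE 0.09), H3f3b (0.65, SE 0.13), Trp53inp1 (0.63, SE 0.09), Hmgb2 (0.51, SE 0.09) and Ccnd2 (0.44, SE 0.07) rose. Resp18 (-0.92, SE 0.20), Mbp (-0.89, SE 0.19), Penk (-0.87, SE 0.11), Gpr6 (-0.84, SE 0.16) and Ptger4 (-0.73, SE 0.09) fell. Slc32a1 (-0.54, SE 0.08), Sst (-0.67, SE 0.12), Vip (-0.62, SE 0.12) and P2ry12 (-0.66, SE 0.14) fell as well, P2ry12 with -0.11 at P0, and Dlx2, a transcription factor of interneuron precursors, rose (0.43, SE 0.10). In total 343 genes passed, 56 higher and 287 lower. With the replicate block 922 passed, including 341 of the 343. Within replicates 1 and 2 alone 51 passed, and within replicates 3 and 4 alone 5. Without wild-type P7 replicate 2, wild-type P7 replicate 1 or heterozygous P7 replicate 4 the counts were 216, 225 and 226. Over the 16 fits that left out 1 array, Dlx2 passed in 5, and among genes named next for their lists Mvd passed in 2, Bub1 in 4, Idi1 and Rrm2 in 7, Gabrd, Syn2 and Tbr1 in 10 and Insm1 in 11. Every other gene named as risen or fallen on average passed in all 16.

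Averaged over the ages, 17 of 37 lists were called, and 7 of these also with an estimated correlation. With the array batch as a block 1 of these 7 kept that call, the inhibitory postsynapse (adjusted p = 0.0283 with an estimated correlation), and the other 6 lost it (adjusted p of 0.0717 or more). The proliferation list had 4 of 29 genes higher, including Mki67 (0.45, SE 0.09), Bub1 (0.44, SE 0.11) and Rrm2 (0.41, SE 0.10), and 12 adjusted over the list alone (adjusted p = 0.0446 with an estimated correlation). Among 12 genes of intermediate progenitors 1 rose, Insm1 (0.44, SE 0.10), and 5 adjusted over the list alone (adjusted p = 0.0446 with an estimated correlation). Of 14 inhibitory postsynapse genes 3 fell, including Slc12a5 (-0.43, SE 0.06) and Gabrd (-0.37, SE 0.08), and 6 adjusted over the list alone (adjusted p = 0.0180 with an estimated correlation). Of 16 genes of myelinating oligodendrocytes 6 fell, also 6 adjusted over the list alone, and all 16 values were negative (adjusted p = 0.0259 with an estimated correlation). Of 25 astrocyte genes 5 fell, including Slc7a10 (-0.47, SE 0.08), and 8 adjusted over the list alone (adjusted p = 0.0446 with an estimated correlation). Of 19 striatal markers 6 fell, including Ppp1r1b (-0.57, SE 0.12) and Pdyn (-0.37, SE 0.08), and 10 adjusted over the list alone (adjusted p = 0.0259 with an estimated correlation). Of 19 sterol genes 3 fell, Tm7sf2 (-0.45, SE 0.09), Mvd (-0.35, SE 0.09) and Idi1 (-0.29, SE 0.07), and 10 adjusted over the list alone (adjusted p = 0.0446 with an estimated correlation). The medians of these 7 lists had the same sign within both array batches.

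For the other 10 lists called on average, the adjusted p with an estimated correlation was between 0.055 and 0.272. Presynaptic vesicles had 4 of 35 genes lower, including Dnm1 (-0.34, SE 0.06) and Syn2 (-0.31, SE 0.07), and adjusted p = 0.055 with an estimated correlation. Voltage-gated channels had 5 of 39 lower, including Scn2b (-0.54, SE 0.08), with adjusted p = 0.055. G1 regulators had 1 of 24 higher, Ccnd2, with adjusted p = 0.055. Of the 73 genes of oxidative phosphorylation 1 fell and 71 had negative values (median -0.10, adjusted p = 0.162 with an estimated correlation). The other lists were splicing factors (median 0.08), autism and intellectual disability genes (0.07), upper-layer neurons (0.07), ribosomal proteins (0.04), histones (0.02, with -0.05 within replicates 1 and 2 and 0.19 within replicates 3 and 4) and thalamus, hypothalamus and midbrain (-0.24). Of their genes, 2 histone genes rose, 1 thalamic, hypothalamic or midbrain gene fell, and in the autism list 1 rose and 2 fell. Adjusted over the list alone these counts were 2, 1, 2 and 3. Among the 20 lists not called, the camera adjusted p was between 0.0603 (olfactory bulb) and 0.754 (endothelial cells and pericytes). With the replicate block radial glia (adjusted p = 0.0316) and glutamate receptors (adjusted p = 0.0205) were also called. Without the block, neither was called with an estimated correlation. Among lists of neurons and signalling, the medians were -0.10 for cortical interneurons (1 gene higher, 4 lower), -0.10 for glutamate receptors (2 lower), 0.01 for deep-layer neurons (Tbr1 higher, Pcp4 lower), -0.08 for calcineurin and NFAT signalling, -0.07 for cAMP and growth factor signalling (1 lower), 0.03 for radial glia, 0.03 for apoptosis and -0.03 for stress and hypoxia response (Ddit4 higher). DYRK, CLK and HIPK kinases had 0.05. Among other cell types and regions, the medians were -0.11 for oligodendrocyte precursors (1 lower), -0.09 for microglia and macrophages (2 lower), -0.07 for endothelial cells, 0.01 for meninges, -0.11 for erythroid cells (1 lower), -0.06 for choroid plexus, -0.10 for hippocampus (1 lower) and 0.12 for olfactory bulb. The medians of neurite growth (-0.02), immediate early genes (-0.01) and protocadherins (-0.01) lay just below 0 while the test pointed up, and the last pair changed sign with quantile normalization again.

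**Figure D2:**
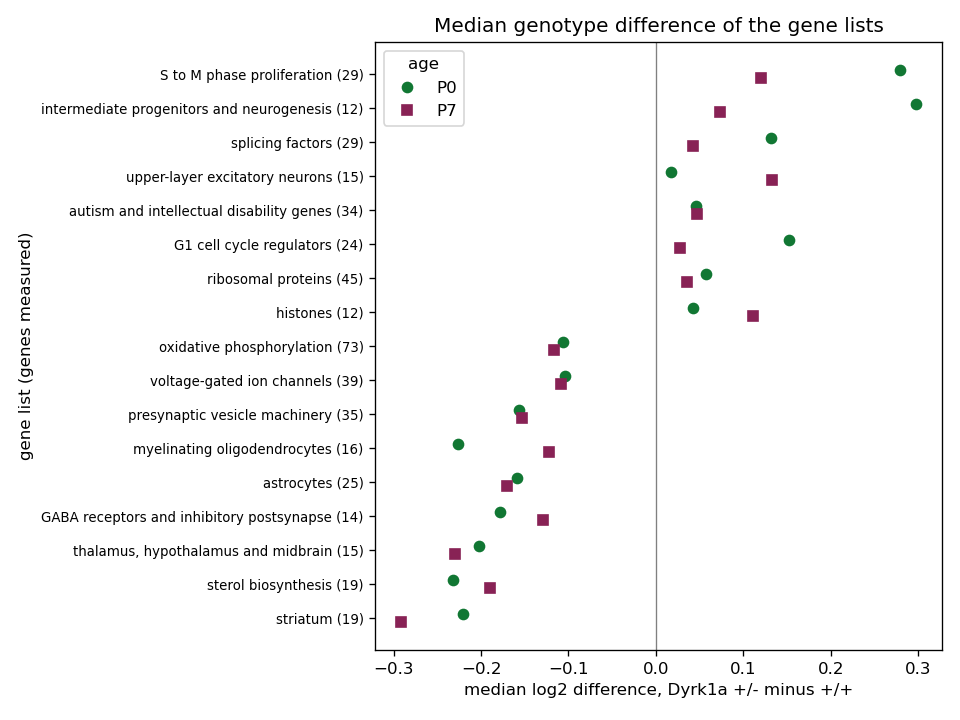
Median log2 difference (heterozygous minus wild type) at P0 (circles) and P7 (squares) of the 17 gene lists called for the mean of both ages, with the number of measured genes in brackets. The S to M phase list had medians of 0.28 at P0 and 0.12 at P7, and the striatal list -0.22 and -0.29.

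Whether the genotype effect changed with age was tested as an interaction. In limma 0 genes passed (smallest adjusted p = 0.228), 995 had an unadjusted p under 0.05, and 0 passed with either block. The lowest p values included the ciliary gene Foxj1, with -0.31 at P0 and 0.30 at P7 (difference 0.61, SE 0.11), and Ak7, another ciliary gene (0.94, SE 0.19). They also included Vsnl1 (0.57), the presynaptic gene Rims2 (0.90), Mobp (-0.71), Sstr2 (-0.65) and Dpy19l1 (-0.86). Asns and Psph, enzymes of asparagine and serine synthesis, had -0.78 and -0.80, and the mitochondrial folate enzyme Mthfd1l -0.48. Of 37 lists 1 was called, S to M phase genes, whose effect was smaller at P7 (median difference -0.23, adjusted p = 0.0232). The median difference was -0.05 within replicates 1 and 2 and -0.34 within replicates 3 and 4. None of its 29 genes passed in limma, also adjusted over the list alone, and the list was lost with an estimated correlation (adjusted p = 0.871).

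Across all genes, the genotype effects at P0 and P7 correlated with r = 0.26 and rho = 0.20, where genes are not independent replicates. Of 100 draws with genotypes permuted within each age, 31 gave an r as large in size (permutation p = 0.317, and 0.446 for rho, two-sided). These draws ignore the replicate pairs; of the 64 arrangements that part every pair, 12 gave an r as large in size (exact permutation p = 0.188, and 0.219 for rho, two-sided). Within replicates 1 and 2 r was 0.34, and within replicates 3 and 4 it was -0.04. Among the called genes, 4 were lower at both ages, Gpr83, Tac1, Tlcd1 and Tmem151a, and 0 were higher at both. Genes are not independent, so the 70 and 22 genes ranked lowest at each age were taken again under the 256 relabellings that part every pair, of which 7 shared 4 or more, the real labels included (highest other 6, exact permutation p = 0.0273, one-sided). These 4 were singled out after their values were seen. Gpr83 had -0.52 at P0, Tlcd1 -0.46 and -0.55, and Tmem151a -0.47 and -0.51. Of the 70 genes lower at P0, 67 had a negative value at P7, and of the 22 lower at P7, 21 had a negative value at P0. Of the 18 higher at P0 and the 6 higher at P7, 16 and 6 had a positive value at the other age. These shares are of called genes, and of all genes 55.6% had the same sign at both ages.

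A developmental score asked where heterozygous arrays lay on the course from P0 to P7. It was the mean log2 of the 500 genes that rose most with age minus that of the 500 that fell most, chosen without regard to genotype. At P0 the score was -1.23 ± 0.16 (SD, n = 4) in wild type and -1.73 ± 0.11 in heterozygotes, a difference of -0.50 (SE 0.10, exact permutation p = 0.0286, two-sided). At P7 it was 1.14 ± 0.03 and 0.84 ± 0.06, a difference of -0.31 (SE 0.03, exact p = 0.0286). This is the smallest p that 4 arrays against 4 allow, and at each age all 4 heterozygous arrays lay below the lowest wild-type array. Without any 1 of the 4 heterozygous P0 arrays the exact p at P0 was 0.0571, with differences from -0.54 to -0.47. The differences amount to -21.1% and -12.9% of the wild-type change of 2.37. Within replicates 1 and 2 they were -0.50 and -0.28, and within replicates 3 and 4 -0.50 and -0.34. Of the 287 genes called lower on average, 247 rose with age in both genotypes and 3 fell, and of the 56 called higher, 45 fell and 3 rose. Of all 12801 genes, 2381 rose and 1953 fell in both genotypes.

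**Figure D3:**
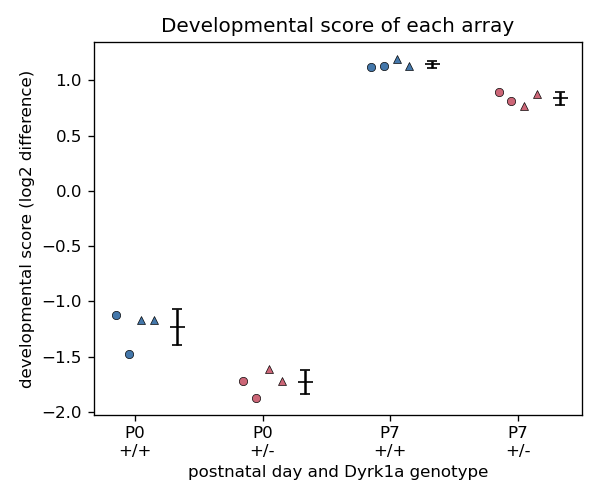
Developmental score (log2 difference) of each array by age and genotype; circles are replicates 1 and 2, triangles replicates 3 and 4, and bars show the mean and SD of 4 arrays. Heterozygous arrays lay between -1.87 and -1.61 at P0 and between 0.76 and 0.89 at P7, below all wild-type arrays of the same age.

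The comparison of ages in wild type asked how the cortex changed over the first week. The middle part of the sample description code was C2 or C3 on all P0 arrays and C1 or C4 on all P7 arrays. Age therefore cannot be told apart from what that code marks, and the code was not used as a block for age. Within each group replicates 1 and 3 shared a code, as did replicates 2 and 4, so the 4 arrays may not be independent. The myelin gene Mbp rose by 4.58 (SE 0.26), the perineuronal matrix gene Hapln1 by 4.05 (SE 0.24), Gpr37l1 by 3.47 (SE 0.25), Vip by 3.25 (SE 0.18), Aqp4 by 2.38 (SE 0.12), Camk2a by 2.37 (SE 0.15) and the glutamate transporter Slc1a2 by 2.36 (SE 0.16). Igfbpl1 (-2.79, SE 0.20), Gpc2 (-2.77, SE 0.22), Sox11 (-2.21, SE 0.10), Insm1 (-1.90, SE 0.14) and the replication gene Mcm7 (-1.51, SE 0.11) fell. The most intense Dyrk1a probe set fell by 0.34 (SE 0.09) in wild type and by 0.47 in heterozygotes. The next most intense had -0.14 (SE 0.18) in wild type, which did not pass, and fell by 1.09 (SE 0.18) in heterozygotes, and the dimmest had 0.22 and 0.03 (SE 0.15), neither passing. In wild type 5236 genes passed, 2874 higher and 2362 lower at P7. In heterozygotes 6194 passed, 3268 higher and 2926 lower. Within replicates 1 and 2 alone the counts were 4470 and 5107, and within replicates 3 and 4 alone 3736 and 4958.

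By list, astrocyte genes rose in 23 of 25 (median 1.23), presynaptic vesicle genes in 23 of 35 (0.70), GABA receptor genes in 11 of 14 (0.59), glutamate receptor genes in 22 of 33 (0.50) and microglial genes in 17 of 21 (0.67). Genes of myelinating oligodendrocytes rose in 12 of 16 and fell in 1. The counts that rose adjusted over the list alone were 23, 26, 11, 23, 19 and 12. All 6 lists were called with an estimated correlation, with adjusted p of 0.00727, 0.018, 0.00748, 0.00727, 0.0318 and 0.0117. S to M phase genes fell in 26 of 29, also 26 adjusted over the list alone (median -0.56), and the list had adjusted p = 3.05e-10, and adjusted p = 0.0706 with an estimated correlation. Ribosomal protein genes fell in 27 of 45, and 31 adjusted over the list alone (median -0.31, adjusted p = 0.0706 with an estimated correlation). Sterol genes rose in 10 of 19, and 12 adjusted over the list alone (adjusted p = 0.109 with an estimated correlation). In all 20 of 37 lists were called, and 10 with an estimated correlation. With the array batch as a block 4 of these 10 lost that call (adjusted p from 0.0535 to 0.0820), microglia (0.0820) being 1 of the 6 lists above.

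A targeted allele can carry linked sequence of another strain, so measured neighbours of Dyrk1a on chromosome 16 (gene order of assembly GRCm38.p6) were compared with all other genes. Of 41 neighbours, 25 before and 16 after the gene, 10 (24.4%) had an unadjusted p under 0.05 for the mean genotype effect, against 16.4% of the others (two-sided Fisher's exact p = 0.201). The only neighbour that passed over all genes was Pcp4 (-0.43, SE 0.09), a calmodulin-binding protein of deep-layer neurons. With up to 50 neighbours on each side the share was 25.8% (exact p = 0.0454), though only the same 16 measured genes lay after Dyrk1a. With no filter on dim genes the share was 24.0% (exact p = 0.0351).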

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

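Chosen only after the result was seen were the tests of array batch, weaker contrast, slower maturation, less striatum, lag of striatal genes and glucocorticoid response, the array batch block, the splits counted with an estimated correlation and all splits and relabellings that part every replicate pair; the FoxO test was written after the gene values but before the list's result was seen, and the other tests of this part were chosen before.

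Heterozygous arrays lay earlier on the course from P0 to P7. Array batch as the cause is argued against by the score differences within batches, of which the one nearest 0 was -0.28, with both heterozygous arrays below both wild-type arrays in all 4 combinations of age and batch. A weaker contrast of the heterozygous arrays would raise the score at P0, where it was lower by more than the larger SD of 0.16 (-0.50), and sex is argued against as the whole cause by a mean difference of -0.41 (SE 0.06) with the Y-linked level as a covariate. Slower maturation of many genes together predicted that genotype effects run against age effects across the 11118 genes on no list and outside the score. There r was -0.54 (rho -0.53, and r of -0.46 and -0.44 within the batches), narrowly outside the range of 100 relabelled draws (-0.48 to 0.43). However, 1 other of the 256 relabellings that part every replicate pair gave a slightly lower value (-0.539 against -0.535). The score used the same arrays and labels, so r is not independent of it. Nor can r tell slower maturation from a different mix of cell types. A lag already present at P0 may explain the lower scores, as a hypothesis. The score difference was smaller at P7 (-0.31) than at P0 (-0.50), so the scores do not show a slower change between these ages. Litter, time of birth and dissection are not in the labels and stay open.

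Striatal markers were lower in heterozygotes. A lag along the age axis as the whole cause is argued against by the 19 measured markers together. Their median distance from the values that the slope over all genes gives was -0.28 (SE 0.06 over the markers, which are not independent). That distance was outside the range of 100 relabelled draws (-0.20 to 0.20). It was also lower than in the other relabellings that part every replicate pair (lowest -0.26), and 17 of 19 markers lay below the values from the slope. Less striatum in the dissected piece stays open. The median of 7 striatal transcripts other than Penk and Tac1 was -0.28 (SE 0.08 over the transcripts), between the values set to favour or exclude it. Without Drd2, a dim gene (mean log2 5.26) left out only after its value was seen, it was -0.36 (SE 0.08 over the transcripts), past the -0.3 set to favour it. All 7 belong to the 19 markers whose fall is in question, so their median restates that fall and cannot decide. The 7 were Ppp1r1b (-0.57), Rxrg (-0.46), Rarb (-0.44), Rgs9 (-0.28), Drd1 (-0.25), Pde10a (-0.17) and Drd2 (-0.14), of which Ppp1r1b and Rxrg passed. A difference in the neurons themselves was not tested, and the cortex also expresses several of these genes.

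Ddit4, Pik3r3 and Trp53inp1 were higher in heterozygotes. A glucocorticoid response stays open. The 11 other glucocorticoid-induced genes had a median of 0.02 (SE 0.06 over the genes, which are not independent). They went both ways, with 6 positive (camera p = 0.384 with an estimated correlation). A candidate explanation is a FoxO target response: 22 FoxO targets without these genes had a median of 0.10, and 19 of 22 were positive (camera p = 0.000842 with an estimated correlation, and 0.00453 with the array batch block). Only Ccng2 of the 22 passed over all genes, and the slope with age would give medians of -0.02 for the FoxO targets and -0.09 for the glucocorticoid genes, so both lists lay above it by similar amounts. Handling and litter stay untested, and this remains a hypothesis.

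Some single arrays stood apart from the other 3 of their group. Of 412 groups of 4 values tested, 28 had such an array, where chance gives about 1 in 20 (20.6). Wild-type P0 replicate 2 held 6 of them: a score of -1.47 (others -1.17 to -1.12), the striatal markers Penk at 7.79 (others 8.43 to 8.53), Drd1 at 8.45 (others 8.69 to 8.72) and Rxrg at 8.40 (others 8.81 to 8.84), Trp53inp1 at 10.98 (others 10.46 to 10.55) and Kcnc4 at 7.84 (others 7.96 to 7.98). Wild-type P7 replicate 3 had a score of 1.19 (others 1.12 to 1.13) and Gabrg1 at 8.01. Heterozygous P7 replicate 1 had Bub1 at 5.95 and Pik3r3 at 9.51, and replicate 4 had Slc6a7 at 11.17 and P2ry12 at 4.83. Single values stood apart for Bub1 at 5.17 in wild-type P7 replicate 1, Tbr1 at 9.57 in heterozygous P0 replicate 2, Mal2 at 7.36 and Rarb at 7.73 in wild-type P0 replicate 1 and Penk at 7.86 in heterozygous P0 replicate 4. Others were Gabrb1 at 10.44 in heterozygous P0 replicate 1, Gpr17 at 8.97 in heterozygous P7 replicate 3, P2ry12 at 7.06 in wild-type P7 replicate 2 and Slc32a1 at 9.15 in wild-type P0 replicate 4. The remaining ones were Sgpp2 at 5.84 in heterozygous P0 replicate 3 and at 8.33 in wild-type P7 replicate 4, Tmem151a at 8.65 in heterozygous P7 replicate 2 and Rcan2 at 9.64 in wild-type P0 replicate 3. The Y-linked gene Eif2s3y stood at 10.54 in wild-type P0 replicate 4, 10.59 in heterozygous P0 replicate 2 and 10.28 in wild-type P7 replicate 3, each the only high array of its group.

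Between the ages, the S to M phase list differed in its genotype effect by the interaction test (camera adjusted p = 0.0232, and 0.871 with an estimated correlation), with median differences of -0.05 within replicates 1 and 2 and -0.34 within replicates 3 and 4. Foxj1 went opposite ways, -0.31 at P0 and 0.30 at P7 (difference 0.61), with an adjusted p of 0.228 for the difference.

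Other splits of the arrays show which counts chance can give. Splits that part every replicate pair keep the array batches balanced between the groups, as the real labels do, and so are the closest comparison. The 8 of them at each age are too few for a share under 0.05. The 88 genes at P0 stood against 0 as the highest of these other splits, the 28 at P7 against 1, the 18 lists at P0 against 14 and the 15 lists at P7 against 8; with the array batch block the 459 genes at P0 stood against 0 and the 246 at P7 against 4. The remaining splits, of 35 in all, keep both arrays of at least 1 pair in the same group: over all 35 the highest other counts were 5 and 67 genes at P0 and P7, 16 and 12 lists, and 222 and 4 genes with the array batch block. The 67 came from the split by array batch, so 2 of 35 gave as many as 28 at P7. For the mean effect, 100 draws that part every pair can reach such a share. Only the real labels, 1 of 100, gave as many as the 343 genes (highest other 24) or the 992 with the array batch block (highest other 209). That is the smallest share these draws allow, so chance rarely gave as many. As many as the 17 lists came from 7 of 100 (highest other 19), so chance cannot be excluded there. The 7 lists called with an estimated correlation came from 1 of 100 (highest other 3), though 6 of them lost that call with the array batch block. Among 100 draws that ignore the pairs, 2 gave as many as 343, the other being 1335, a draw that largely follows the array batches, 1 as many as 992 (highest other 117) and 3 as many as 17 lists (highest other 19). For the genes of age in wild type (5236, 1 of 35, highest other 0) and in heterozygotes (6194, 1 of 35, highest other 1), only the real split gave as many. The same holds for the 10 lists of age in wild type called with an estimated correlation (1 of 35, highest other 0), while the count of 20 with the preset one (3 of 35, highest other 20) decides nothing, since the 16 splits that divide the ages 3 to 1 gave 15 to 20. Chance cannot be excluded for the 995 genes at an unadjusted p under 0.05 for the interaction (11 of 100 that part every pair, highest other 2098, and 17 of 100 that ignore pairs, highest other 2463).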

How the results depend on the processing

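The within-batch fits, the array batch block (also with an estimated correlation), the arrangements that part every pair for the correlation of effects and the score without listed genes were chosen after the data were seen. All other alternatives were planned. The test of RNA integrity and its covariate could not be run for lack of control probe sets, and the pseudocount alternative did not apply to log2 values. Where not stated otherwise, the cause of a change was not tested.

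Over 298 values that answer a comparison, 236 stayed, 48 counts moved, 10 values weakened, 2 strengthened and 2 reversed. Tests stayed if they kept their direction and side of the threshold. Counts stayed if within 1.5 times of the main count, or at 0 where that was 0, whatever their split by direction. Over 9773 values of named genes, 8723 stayed, 850 weakened, 200 strengthened and 0 reversed. With the replicate block the counts at P0, at P7 and for the mean effect were 386, 101 and 922, and with the array batch block 459, 246 and 992. Age counts were 6561 in wild type and 7524 in heterozygotes with the replicate block and 6457 and 7431 with the array batch block, within 1.5 times of 5236 and 6194, and the interaction stayed at 0. With only the 8 arrays compared they were 0 at P0 and 7 at P7, where fewer arrays estimate the spread. Replicates 1 and 2 alone gave 1, 3 and 51, and replicates 3 and 4 alone 0, 3 and 5, with fewer samples. At P0 the mean of all probe sets gave 137, 52 of them higher. At P7 the code block gave 12 and the Y-linked covariate 10. With every probe set tested on its own, age gave 11418 in wild type and 14287 in heterozygotes, since more features were tested.

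Leaving out 1 array gave 14 to 107 genes at P0, 3 to 19 at P7 and 216 to 374 for the mean effect, with fewer samples. Of the named genes that passed, 9 of 34 at P0, 1 of 18 at P7, 46 of 70 for the mean effect, 155 of 159 for age in wild type and 20 of 20 in heterozygotes passed whichever array was left out. The interaction stayed at 0 under all settings. For the dimmest probe set of Dyrk1a at P7 the difference ranged from -0.16 to 0.038, with 0.0099 and 0.038 without heterozygous replicates 1 and 2. The score difference at P0 ranged from -0.56 to -0.44. Within the batches it was -0.50 and -0.50 at P0 and -0.28 and -0.34 at P7, and permuting genotypes within the replicate block left -0.50 and -0.31, where the smallest exact p these designs allow is over 0.05.

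Lists called with an estimated correlation numbered 1 at P0, 0 at P7, 0 for the interaction, 7 for the mean effect and 10 for age in wild type, and with the array batch block as well they numbered 0, 0, 0, 1 and 6. Fry called 11 at P0, 0 for the interaction and 32 for age. The mean of all probe sets gave 0 for the interaction. The share of Dyrk1a neighbours was 25.8% with up to 50 genes on each side and 24% with no filter. In the age comparison of wild type, intermediate progenitors lost their call with the replicate block (adjusted p = 0.0772). Beside those given with the results, the replicate block changed no other list call. Signal limits remained for the 5392 genes left out as dim.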

Other observations

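The test of the amino acid genes was written after the gene values but before the list's result was seen. Several other genes and lists separated the ages in wild type. The neurotrophin gene Bdnf rose by 1.42 (SE 0.11), the immediate early gene Egr1 by 1.60 (SE 0.17), the peptide gene Cck by 1.85 (SE 0.14) and the receptor subunit gene Gabra4 by 1.40 (SE 0.09). The immediate early list had 12 of 19 genes higher and 1 lower (adjusted p = 0.000164, and adjusted p = 0.109 with an estimated correlation). Dcx had -0.91 (SE 0.09), Nes -0.80 (SE 0.12) and Hmgb2 -1.06 (SE 0.13), and all 3 passed. Splicing factors fell in 16 of 29 and rose in 1 (adjusted p = 7.23e-05, and adjusted p = 0.0754 with an estimated correlation). Autism and intellectual disability genes fell in 21 of 34 and rose in 3, and that list was called with an estimated correlation (adjusted p = 0.0248), a call lost with the array batch as a block (adjusted p = 0.0820 with an estimated correlation). Rcan2, an inhibitor of calcineurin, had -0.49 at P0 in heterozygotes and -0.36 on average, and did not pass over all genes.

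Asns, Psph and Mthfd1l had lower genotype effects at P7 than at P0, though none passed. A response of ATF4 targets may account for this, as a hypothesis: 25 other ATF4 targets had a median difference of -0.19, and 6 of 25 were positive (camera p = 0.0275 with an estimated correlation, and 0.00787 with the array batch block). None of the 25 passed in limma.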
